A study of Homo sapiens with 2 samples.

How the data were processed

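Gene expression was measured in total RNA of C4-2B cells, an established human prostate cancer cell line, with an Affymetrix whole-transcript array, Human Gene 2.0 ST. This array reads each gene through probes spread along its exons, summarised per transcript cluster (the array's unit for a gene locus). The labels give 2 groups with 1 array each: a line infected with the control lentivirus and a line infected with a lentivirus carrying a short hairpin RNA against KDM4B. The values are log2 expression, which the authors deposited with 2 decimals. Per the submitters' processing notes they were made with Transcriptome Analysis Console and RMA, which corrects the background, makes the probe distributions of the arrays alike and summarises the probes of a cluster. The versions of these tools and the settings used are not given in the sources used here. It is therefore unknown whether a form of RMA that stretches the signal scale was used, and the sizes of the folds and the meaning of the level of 5 depend on that. Per the file headers the annotation is release na36 on the hg19 genome, and all coordinates printed here are from it.

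A second table that the authors deposited holds their own comparison of the 2 arrays as signed fold changes, with a fold below 1 written as minus its reciprocal. The p-values and adjusted p-values that the authors deposited there are 1 for all 48226 clusters and no standard deviation is given, so they were not used as tests. Per the file headers the knockdown arm of that table is named sh8, whereas the sample label names it sh4B. Its 2 columns of log2 averages were equal to the value table in all 48226 clusters, which ties the annotation to the values. The samples were taken from the value table, whose columns carry the sample identifiers.

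Of the 48226 clusters, 29205 had 1 gene symbol in the deposited table, 1923 had several and 17098 had none. The last 2 kinds entered no gene value. Symbols were brought up to date with a RefSeq gene table of GRCh38.p14, used for names and gene types only: 24425 clusters had a current symbol, 2199 were renamed through a RefSeq accession, 234 through an older symbol, and 2347 kept the name in the file. One value per gene was taken from the cluster with the highest mean of both arrays, which gave 27858 symbols. Of these, 8129 had a log2 value of at least 5 in at least 1 array and were analysed, among them 7483 protein-coding genes. Detection calls were not used here, so the level of 5 is a filter on dim probes and not a measured background. The median of all clusters was 2.61 in both arrays.

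The difference of a gene is its knockdown value minus its control value on the log2 scale, with no further normalization. With 1 array per group there is no estimate of the spread between cultures, so no SD or standard error between arrays and no p-value is given, and the number of arrays limits the precision. Because the deposited values are rounded, a difference can be off by 0.01. In place of a test, genes were counted at a fixed size of 1.5-fold and again at 2-fold. For 33 gene lists, the median difference of the members past the level was ranked among 10000 random lists of the same size, drawn from the 8129 genes in 20 bins of mean signal. A list was said to stand apart when its percentile was at most 2.5 or at least 97.5. Lists with fewer than 5 such members got no percentile, which left 27 lists, of which about 1.4 would fall outside the central 95% by chance if genes varied independently. Genes of a pathway vary together between any 2 cultures, so such a percentile describes these 2 arrays and is not a test of the knockdown. Several lists share genes.

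The lists, the level, the thresholds and the alternatives were fixed before the data were examined, as was the rule for the genes named. The rule names KDM4B, KDM4A, KDM4C, KDM4D, MYC, KLK3 and LDHA. It adds the 12 protein-coding genes with the largest difference in each direction, and for each list that stood apart the 4 members with the largest difference in that direction. From each other list it takes at most 3 members that differed at least 1.5-fold. Where the report gives a count of 5 or fewer higher, lower or equal genes, it names them. The values of 3 genes that the rule selects are not reported here. A gene that the RefSeq table does not hold counted as protein-coding unless its symbol marked a noncoding RNA, which applied to CDR1.

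The alternatives were the mean over a symbol's clusters, no minimum level, a level of 6, a level of 5 in both arrays, centring on the median difference, an added quantile normalization, subtraction of a loess trend on mean signal with a span of 0.4, and the authors' deposited fold changes in place of the value table. For counts they also included the 2-fold threshold and protein-coding genes alone. For lists they included the mean of the members, 50 bins, a protein-coding background, and members shared with another list left out. Leaving KDM4B out of the hypoxia list was added after seeing the data. The steps were tested on simulated data for this comparison of control and knockdown, run on 8129 genes. Each gene was drawn independently from a normal distribution, with a spread set by the median absolute deviation in its bin of mean signal. The simulated lists were random genes that did not vary together, so the rates do not carry over to pathway lists. Of 100 genes changed 2-fold, 98 passed the 1.5-fold threshold in their direction, as did 100 of 100 changed 3-fold and 48 of 7929 unchanged genes. Of 200 lists of 25 genes, 8 fell outside the central 95% with no shift, 126 with a shift of 0.1 and 200 with a shift of 0.2 on the log2 scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.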

Results

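The series compared the transcriptome of C4-2B prostate cancer cells carrying a control lentivirus with that of the same cells after lentiviral knockdown of KDM4B, a histone demethylase that removes methyl groups from lysine 9 of histone H3. C4-2B is a castration-resistant derivative of the androgen-sensitive LNCaP line. The question was which genes differ when KDM4B is knocked down in these cells. The knockdown group is 1 line, so effects of its hairpin on other genes cannot be told apart from loss of KDM4B. The same holds for other differences between the 2 infected lines. Each group was measured on 1 array, so no value below has a replicate error and the differences are those between these 2 arrays. The arrays had like distributions, with a median of 2.61 and upper quartiles of 4.59 in the control and 4.58 in the knockdown array on the log2 scale. Across the 8129 genes past the level of 5, the Pearson correlation between the arrays was 0.987, a value across genes, which are not independent replicates.

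KDM4B signal was lower in the knockdown array, at 5.80 against 6.56 on the log2 scale, a difference of -0.76 or 1.69-fold. The gene lies on chromosome 19 from 4969124 to 5153609 on the plus strand (hg19). It had the 11th most negative difference of the 7483 protein-coding genes. The authors' deposited table lists it as 1.7-fold lower. Among the other members of its family, KDM4A differed by -0.11, at 6.54 against 6.65, and KDM4C by 0.02, at 4.85 against 4.83. KDM4C had 2 clusters, whose average differed by 0.17. KDM4D was dim in both arrays, at 2.97 in the control and 3.04 in the knockdown. Of the 2 members past the level, KDM4A and KDM4B, only KDM4B differed at least 1.5-fold. The 15 other histone demethylases past the level had a median difference of 0.02 and no member at 1.5-fold. The 11 histone H3 lysine 9 methyltransferases and heterochromatin proteins past the level had a median of 0.11, within the range of random lists.

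Few genes differed by a large factor. Of the 8129 genes, 40 were at least 1.5-fold higher and 61 at least 1.5-fold lower in the knockdown array. At 2-fold the counts were 3 higher and 5 lower. The 3 were H2BC14, P2RY8 and the small nucleolar RNA SNORA2A, which at 1.77 had the largest difference of all. The 5 were GDF15, CHAC1, CDR1, CMPK1 and CAMK2N1. The middle of the distribution was narrow, with a median difference of 0.01 and quartiles of -0.10 and 0.13. The spread over genes grew towards dim signals, from an SD of 0.15 for genes with a mean of 9 or more to 0.21 for those with a mean from 5 to 6. Over all clusters, dim ones included, the authors' deposited table lists 1128 folds of at least 1.5 higher and 1027 lower. Without a minimum level the gene counts were 481 higher and 452 lower, and with the level required in both arrays they were 20 and 32.

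GDF15, a stress-induced cytokine of the TGF-beta family, had the most negative difference, at 7.37 in the knockdown against 8.80 in the control array, 2.69-fold lower (chromosome 19, 18496968 to 18499988). CHAC1, a glutathione-degrading enzyme induced by ATF4, was 2.38-fold lower at 4.67 against 5.92. CDR1, on the X chromosome, was 2.31-fold lower at 6.33 against 7.54. CMPK1, the kinase that phosphorylates UMP and CMP, was 2.07-fold lower at 7.13 against 8.18, and CAMK2N1, an inhibitor of the kinase CaMKII, was also 2.07-fold lower. PRRG2 differed by -0.92. SLC7A11, the cystine transporter, was 1.87-fold lower at 7.43 against 8.33. Its signal came from the brightest of 3 clusters, and averaging all of them gave a difference of -0.18 in place of -0.90. VAMP4 followed at -0.80, SLC10A7 at -0.79, and POTEF at -0.75, equal to STARD4 at 2 decimals. POTEF belongs to a family of near-identical copies, so its value is uncertain. Of the 12 genes with the most negative differences, KDM4B among them, 7 were under the level of 5 in the knockdown array.

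H2BC14, a replication-dependent histone H2B gene, had the most positive difference of the protein-coding genes, at 9.05 in the knockdown against 7.84 in the control array, 2.31-fold higher (chromosome 6, 27782822 to 27783267). Histone H2B genes are near-identical in sequence, so which copy gave the signal is uncertain. NRP1, a co-receptor for semaphorins and VEGF, was 1.71-fold higher at 7.28 against 6.51. SLC6A8, the creatine transporter, was 1.88-fold higher at 5.91 against 5.00. The other 9 of the 12 highest were under the level of 5 in the control array. They were P2RY8 (difference 1.02), MACROH2A2, a histone variant associated with silent chromatin (0.88), TTR (0.86), TTN (0.86), GRIN3A (0.79), NLGN1 (0.77), RBM38 (0.76), BEND4 (0.72) and RPL32 (0.70). P2RY8 lies in the region shared by the X and Y chromosomes and had 2 clusters, whose average differed by 0.62.

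**Figure D1:**
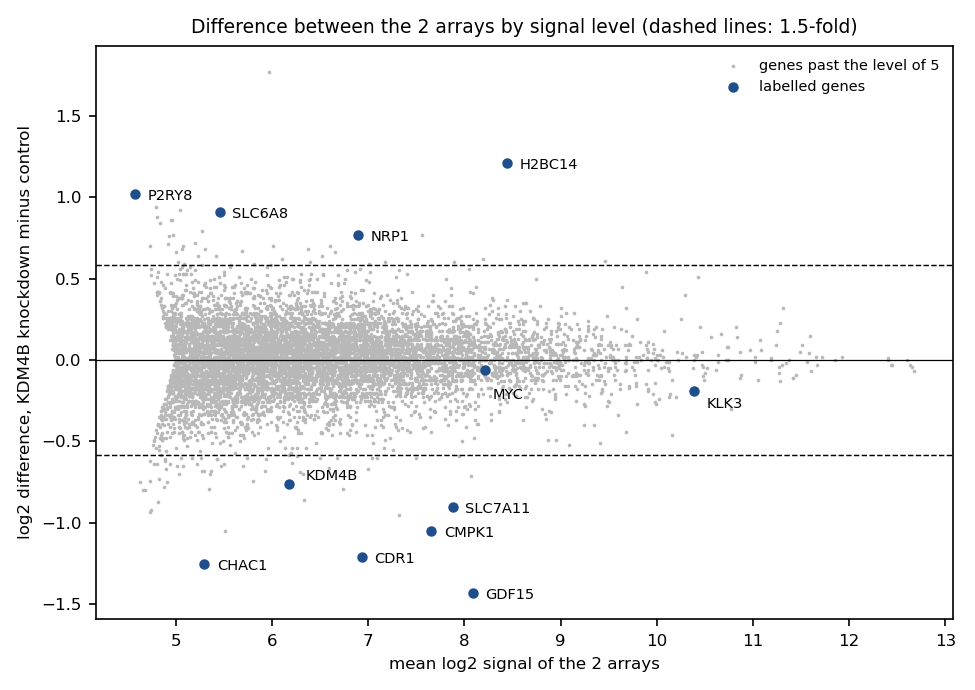
Log2 difference (knockdown minus control, vertical axis) against the mean log2 signal of both arrays (horizontal axis) for the 8129 genes past the level of 5; grey points are genes, blue points are labelled genes, and dashed lines mark 1.5-fold. KDM4B lies at -0.76, GDF15 at -1.43, H2BC14 at 1.21 and MYC at -0.06.

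Genes of the integrated stress response, the program run by the transcription factor ATF4 under amino acid shortage or other stress, were lower together. Of the 25 members past the level, 23 were lower and 2, SLC7A5 (0.04) and VLDLR (0.15), higher, and 7 were at least 1.5-fold lower with none as much higher. The median difference was -0.34, a fold of 1.27, against a central 95% of -0.06 to 0.09 in random lists, and 0 of the 10000 random lists were as low. Beside CHAC1 and SLC7A11, the 4 most negative members included MTHFD2, the mitochondrial folate enzyme, at 6.66 against 7.33 (difference -0.67), and TRIB3, an ATF4-induced pseudokinase, at 5.63 against 6.24 (difference -0.61). The list is not independent of the glutamine list, with which it shares ASNS, GPT2 and SLC3A2 among others. Endoplasmic reticulum chaperones, the targets of the unfolded protein response, had a median of -0.04 over 19 members and a percentile of 9.7. The heat shock list had a median of 0.03.

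Lipid synthesis genes were also lower. Of the 14 genes of fatty acid synthesis past the level, 12 were lower, 1 higher (ELOVL1, 0.22) and 1 equal (ELOVL6), with a median of -0.23 that 0 of the 10000 random lists reached. ACSL1, which activates long-chain fatty acids, was 1.64-fold lower at 7.71 against 8.42. ACSL3 was at 9.93 against 10.39, ACSS2, which makes acetyl-CoA from acetate, at 5.34 against 5.75, and FASN, the fatty acid synthase, at 9.15 against 9.55. Of 19 cholesterol synthesis and sterol regulation genes, 12 were lower and 6 higher, with a median of -0.16 that 5 of the 10000 random lists reached. STARD4, a sterol transport protein, was 1.68-fold lower but dim, at 4.25 against 5.00. MVD (-0.46), INSIG1 (-0.39) and IDI1 (-0.35) followed.

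Androgen-responsive genes were slightly lower, with 19 of 29 lower, 10 higher, a median of -0.09 and a percentile of 0.1. PMEPA1 was 1.52-fold lower at 6.79 against 7.39 and was the only member at 1.5-fold. ACSL3 differed by -0.46, CENPN by -0.40 and TMPRSS2 by -0.31. KLK3, which encodes prostate-specific antigen, was at 10.29 against 10.48, a difference of -0.19. Luminal epithelial markers had a median of 0.02 over 15 members, within the range of random lists.

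Central carbon metabolism differed little apart from some amino acid genes. The glycolysis list had a median of -0.01 over 22 members and a percentile of 27.6, with no member at 1.5-fold. LDHA, the lactate dehydrogenase subunit, was at 5.24 against 5.08, and this cluster was dim for so abundant an enzyme. Several other members of the glycolysis list were also close to the level of 5. The tricarboxylic acid cycle (median 0.00, 27 members), the pentose phosphate pathway (0.01, 9 members) and oxidative phosphorylation (0.02, 40 members) lay within the range of random lists. COX8A, a subunit of cytochrome c oxidase, was the only member of these lists at 1.5-fold, at 9.77 against 9.16. Of 16 genes of glutamine metabolism, 9 were lower and 7 higher, with a median of -0.10 and a percentile of 0.6. The members at 1.5-fold were GPT2, the mitochondrial alanine transaminase, at 6.74 against 7.34, and ASNS, the asparagine synthetase, at 7.20 against 7.80. SLC1A5 (-0.27) and SLC3A2 (-0.25), subunits of amino acid transporters, followed. The 7 higher members included CAD (0.35), GLUD1 (0.24), GLUL (0.23) and GLS2 (0.22), so the list did not move as 1 group. With the mean of the members in place of the median, the percentile of the glutamine list was 3.2, within the central 95%.

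Proliferation genes were higher together in the knockdown array. Of 43 E2F targets and replication genes past the level, 41 were higher and 2 lower (POLE2, -0.09, and UHRF1, -0.02), with a median of 0.34, a fold of 1.27, against a random range of -0.04 to 0.08. None of the 10000 random lists was as high. E2F8, a repressor of the E2F family that is itself an E2F target, was 1.62-fold higher at 6.95 against 6.25. DTL, a subunit of a replication-coupled ubiquitin ligase, was 1.52-fold higher at 8.19 against 7.59. MCM4, a subunit of the replicative helicase, was at 8.33 against 7.77, and CCNE2, a G1/S cyclin, at 6.79 against 6.27. Mitosis genes gave 38 of 44 higher and 5 lower (HMMR, NUF2, CDC25C, NUSAP1 and TTK, by 0.05 or less), with a median of 0.19, likewise above all of the 10000 random lists. KIF20A, a kinesin of cytokinesis, was 1.54-fold higher at 8.50 against 7.88. SPC25 (0.50), UBE2C (0.44) and AURKB (0.43) followed.

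Nucleotide synthesis and double-strand break repair genes were also higher. Of 23 nucleotide synthesis genes 18 were higher, with a median of 0.18 that 0 of the 10000 random lists reached. They were led by TYMS (0.37), RRM2 (0.36), CAD (0.35) and CTPS1 (0.32), while MTHFD2, at -0.67, was in this list too. RRM2 had 2 clusters, whose average differed by 0.13. Double-strand break repair genes were higher in 26 of 31 cases, with a median of 0.16 that 1 of the 10000 random lists reached. The 4 lower ones were XRCC4 (-0.27), LIG4 (-0.22), RAD50 (-0.18) and ATM (-0.16), and MRE11 was equal. The largest differences of the repair list were in EXO1 (0.49), XRCC2 (0.45), BARD1 (0.37) and FANCA (0.36). EXO1 had 2 clusters, whose average differed by 0.15. Of the 41 histone genes with a value, 21 were past the level, 13 of them higher and 7 lower, and their median of 0.08 was within the random range at a percentile of 94.0. With no minimum level the median was 0.13 at a percentile of 99.8, above that range. H2BC14 and H3C1, at 6.71 against 6.03, were the members at 1.5-fold. The p53 target list had a median of -0.04 and a percentile of 8.9, with GDF15 as its 1 member at 1.5-fold.

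MYC itself did not differ by much, at 8.18 against 8.24. Of 42 MYC target genes past the level, 38 were higher and 4 lower (TBRG4, SORD, PES1 and ODC1), with a median of 0.18 above all of the 10000 random lists, and none reached 1.5-fold. MCM4 (0.56), the ribosome assembly factor NOP16 (0.50), CDC20 (0.42) and TCOF1 (0.38) led, of which MCM4 and CDC20 are also in the replication or mitosis list. Splicing factors were higher in 31 of 36 cases, with a median of 0.12 and a percentile of 99.9. HNRNPA1 was at 7.60 against 7.05 and SNRPD1 at 7.87 against 7.47, followed by PTBP1 (0.25) and SF3A1 (0.25). Cytosolic ribosomal protein genes were higher in 44 of 60 cases with a median of 0.08 and a percentile of 99.8, led by RPL32 (0.70), RPS4X (0.53), RPS28 (0.32) and RPS15A (0.29). With a level of 6 the percentile of this list was 97.1, within the central 95%. These families have many processed pseudogenes, so the values of single members are uncertain. The RPS28 value came from a cluster on chromosome 11 at 82400570 to 82400967, and the average of its 2 clusters differed by 0.20. Reference genes had a median of 0.11 over 16 members and a percentile of 97.1, close to the limit, so the smallest shifts among these lists are of the size seen in reference genes.

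**Figure D2:**
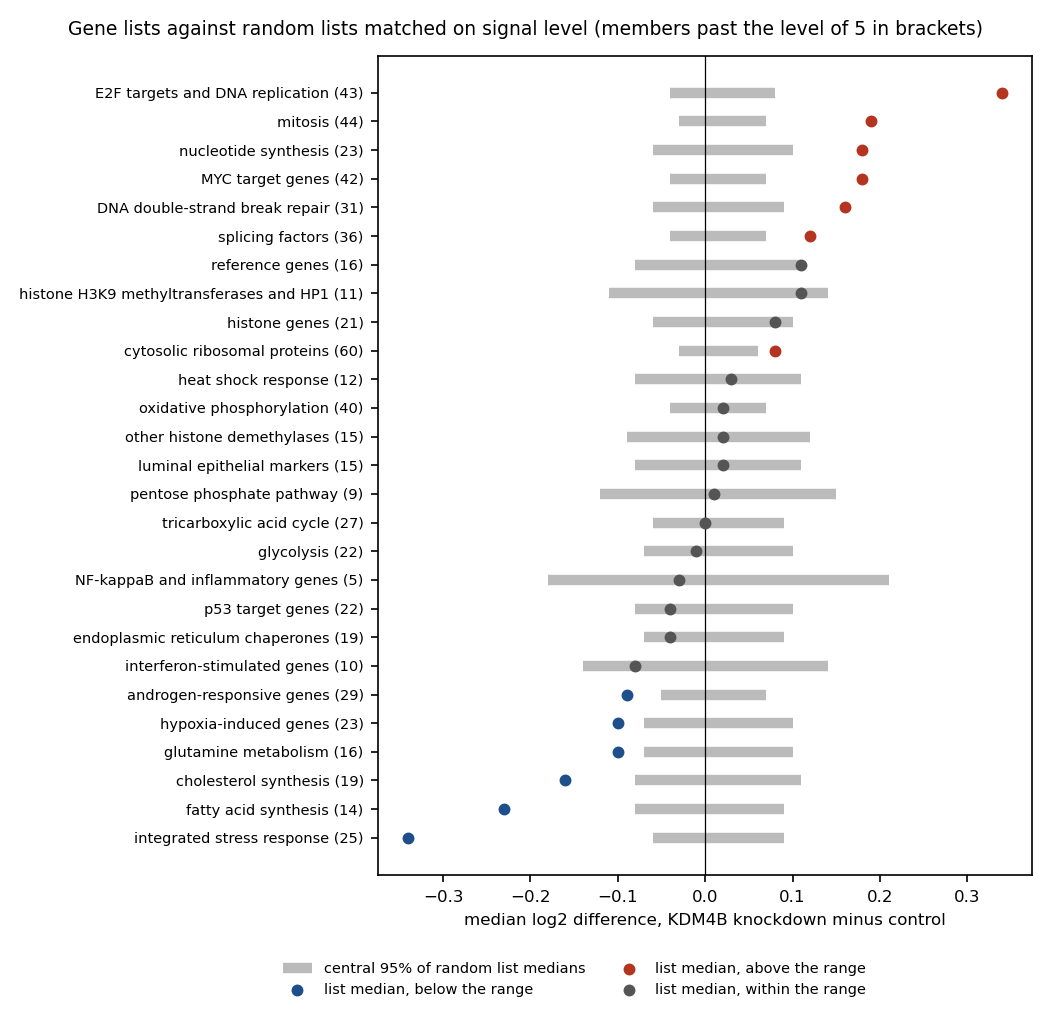
Median log2 difference (knockdown minus control, horizontal axis) of 27 gene lists (rows, with the number of members past the level of 5); grey bars are the central 95% of 10000 random lists matched on signal, and blue, red and grey points are medians below, above and within it. The integrated stress response lies lowest at -0.34 and E2F targets and DNA replication highest at 0.34.

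Hypoxia-induced genes were lower in 17 of 23 cases, with a median of -0.10 and a percentile of 0.4. The list holds KDM4B, and without it the percentile was 1.1. DDIT4, an inhibitor of mTORC1 that is also an ATF4 target, was 1.52-fold lower at 6.38 against 6.98. ANKRD37 (-0.34) and INSIG2 (-0.33) followed. Interferon-stimulated genes, which lentiviral infection can induce, had 10 members past the level, a median of -0.08 and a percentile of 12.9. Of the 26 genes of the NF-kappaB and inflammatory list with a value, 5 were past the level (NFKBIA, NFKB1, NFKB2, CXCL2 and ICAM1), with a median of -0.03.

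Most markers of other cell types were under the level of 5 in both arrays. The basal, mesenchymal, neuroendocrine, leukocyte and endothelial lists had median signals between 2.29 and 2.75 in the control and between 2.41 and 2.58 in the knockdown array. Members past the level were ITGA6 (difference 0.02), FN1 (0.12), SNAI2 (0.05), ONECUT2 (0.01) and CD68 (-0.01), and there was none in the endothelial list. The 10 clusters with named mitochondrial genes differed by -0.08 to 0.01.

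**Figure D3:**
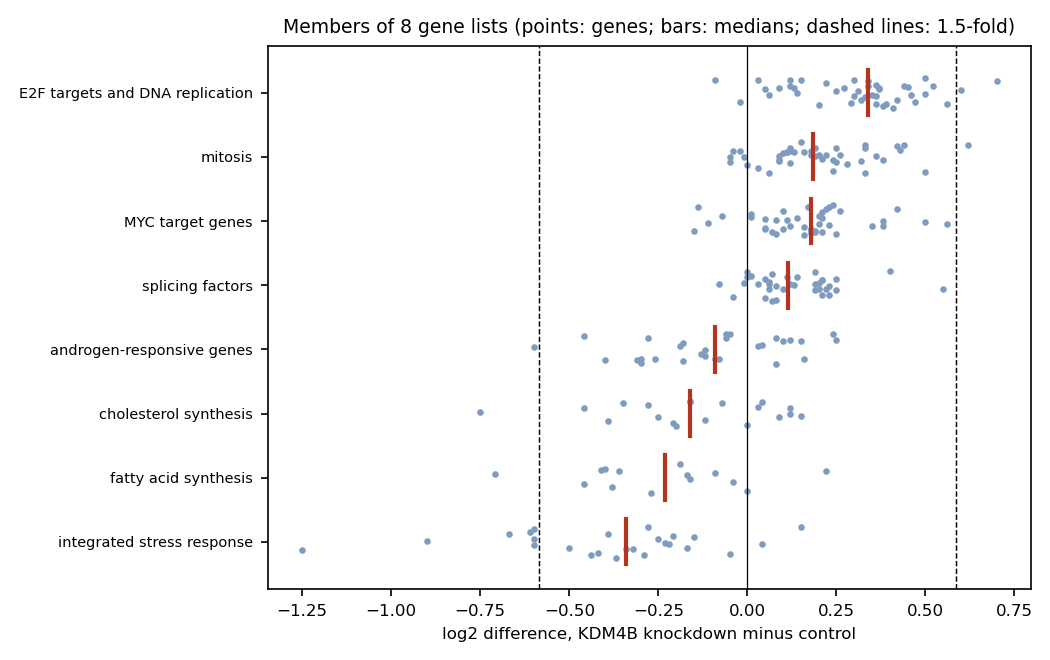
Log2 difference (knockdown minus control, horizontal axis) of each member past the level of 5 in 8 gene lists (rows); points are genes, red bars are medians and dashed lines mark 1.5-fold. Of 25 integrated stress response genes 23 lie below 0, and of 43 E2F target and replication genes 41 lie above 0.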

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

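Signal outside the gene-level comparison was found in transcript clusters that the deposited table pairs with no gene or with several. Of 570 clusters without a symbol on the assembled chromosomes that passed the level of 5, 3 were at least 2-fold higher in the knockdown array and 1 was at least 2-fold lower. The largest difference was 1.77, at 5.49 against 3.72, in a cluster on chromosome 11 from 2357487 to 2363246 (hg19, plus strand). The other higher ones lay on chromosome 5 from 11027312 to 11027419 (difference 1.27) and on chromosome 9 from 33868538 to 33868663 (1.04), and the lower one on chromosome 4 from 139732832 to 139732920 (-1.40). Among 653 clusters with several symbols, the 1 that was at least 1.5-fold higher covered TGFB2 and TGFB2-OT1, with a difference of 0.93 at 6.37 against 5.44. The 2 that were as much lower covered SNORA11 with MAGED2 (-0.86) and ADM2 with MIOX (-0.61).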

How the results depend on the processing

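No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The counts of 40 genes higher and 61 lower depended on the filter: they were 481 and 452 with no minimum level, 18 and 27 with a level of 6, 20 and 32 with the level of 5 in both arrays, and 3 and 5 at the 2-fold threshold, where fewer or dimmer genes enter by construction. Under the other settings tried they stayed within 1.5 times of these counts. The KDM4B difference moved by less than 0.1 under all 5 settings run on it, but most of these could move it little. KDM4B had 1 cluster, so the mean over clusters could not change its value, and centring subtracted only 0.01. Of the 13 lists that stood apart, 11 did so under every alternative run. The percentile of the glutamine list was 3.2 with the mean of the members, and that of the ribosomal protein list 97.1 with a level of 6. Lists within the random range that left it were the histone genes, at 99.8 with no minimum level, 97.8 after loess and 98.3 with the mean, the p53 targets, at 0.6 with a level of 6, and the reference genes, at 97.8 with a level of 6, 97.6 after loess, 97.6 with the mean and 97.8 with 50 bins. The cause of these shifts was not tested. In all, 313 of 323 list values kept their side of the limits, and no list that stood apart changed direction. Centring cannot change a percentile, so its values were kept by construction. The deposited folds differed from the value table by at most 0.016, and the loess trend was at most 0.05 in size. Neither setting could shift a list median by more than 0.05. Every setting used the same 2 arrays, so these counts do not show how a list would vary between cultures. Of 415 values of single named genes, 409 moved by less than 0.1 and none of those at 1.5-fold changed sign. The 6 that moved were all of the named genes with several clusters, each under the mean over clusters. That setting could not change the other genes, and centring, loess and the deposited folds could shift a value by at most 0.05. The 409 kept values were thus mostly fixed by construction. The interferon and NF-kappaB lists had fewer than 5 members at a level of 6 and gave no value there. The authors' deposited table holds 2155 folds of at least 1.5 in either direction and the rounded values give 2122.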

Other observations

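The noncoding RNA classes and chromosomes, and the tests of culture growth state, endoplasmic reticulum stress and small RNA yield, were chosen after the data were seen. Small nucleolar RNAs, which guide the chemical modification of ribosomal RNA, were slightly lower as a class in the knockdown array. Of 83 past the level of 5, 55 were lower and 25 higher, with a median of -0.10 that 0 of 10000 matched random lists reached. The box H/ACA members had a median of -0.10 over 31 genes and the box C/D members -0.09 over 52. SNORD63 (-0.59), SNORA46 (-0.56) and SNORA60 (-0.87) were among the lowest. Some went the other way: SNORA2A was 3.41-fold higher at 6.85 against 5.08, SNORA65 1.71-fold higher at 7.94 against 7.17, and SNORA23 was at 10.16 against 9.62. Among long noncoding RNAs, NEAT1, the scaffold of nuclear paraspeckles, was 1.93-fold lower at 6.85 against 7.80, and the class median was -0.01 over 197 genes. By chromosome, the 433 genes of chromosome 16 had a median of -0.05 (0 of 10000 random lists as low; -0.04 before and -0.06 after the largest gene-free gap), and the 446 of chromosome 3 had 0.05 (7 of 10000 as high; 0.02 and 0.06), while the other 21 of 23 chromosomes lay within the central 95%.

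Of the 25 integrated stress response genes 23 were lower. A trend of the difference with signal level was at most 0.05 in size, against a list median of -0.34. That gap argues against such a trend as the cause. Subtracting the trend left the list at a percentile of 0.0. The random lists were already matched on signal, so that percentile adds little. The chaperone list had a median of -0.04 and lay inside the random range. Of its 19 members 13 were lower and 5 higher (SYVN1, DNAJB11, MANF, CALR and HYOU1, by 0.14 or less). A fall near the -0.34 of the stress response list was thus absent in the chaperone genes. A smaller decrease in endoplasmic reticulum stress stays open. The growth state of the 2 cultures, such as their density or the age of their medium, cannot be told apart from the knockdown with 1 array per group.

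Replication and mitosis genes were higher, with medians of 0.34 and 0.19, and the level-dependent normalization trend was at most 0.05 in size. With it subtracted the medians were 0.32 and 0.17, which argues against that trend as the cause. Then 0 of 10000 random lists were as high for either list. These random lists were already matched on signal, so that count adds little. With members shared with another list left out, the median of the replication list was 0.33. The growth state of the 2 cultures, with 1 array per group, cannot be told apart from the knockdown here either, and a faster-cycling culture could give this pattern. The direction is a point to follow up, since it puts proliferation genes higher where the KDM4B signal was lower.

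For the lower small nucleolar RNAs, the trend with signal level was at most 0.05 in size, against a class median of -0.10. Subtracting it left the class at a percentile of 0.0, which adds little because the random lists were already matched on signal. Lower expression of the genes whose introns carry them was tested in the 47 with a host gene past the level. These had a median of -0.09, while their 39 host genes had a median of 0.07, with 26 higher and 12 lower. Of the 29 lower ones, 20 had a host that was higher or equal, and the others had a lower host. Those with a lower host were SNORA13, SNORA14B, SNORA37, SNORA46, SNORA50A, SNORA54, SNORA5A, SNORA71D and SNORD71, all box H/ACA members except SNORD71. The other lower box C/D members had a higher host, which argues against lower host RNA as the cause for them. Hosts of the lower box H/ACA members went both ways, so lower host RNA stays open for that group. The array reads host exons, so transcription of the hosts was not measured. A lower yield of small RNAs in the knockdown sample stays open, because the other small RNA classes do not decide it. Small nuclear RNAs had a median of -0.07 over 17 genes. At a percentile of 3.5 this lay inside the random range of -0.08 to 0.10. MicroRNA genes had a median of 0.01 over 82, of which 6 were at least 1.5-fold lower and 0 as much higher. The knockdown itself as the cause was not tested.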
